A study of Mus musculus with 14 samples.

How the data were processed

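RNA sequencing was carried out on KL974, a mouse acute myeloid leukemia (AML) cell line whose labels give a mutant Trp53 and hairpins against Mll3 (also called Kmt2c) and Nf1. The cells were grown with the cytokines IL3, IL6 and SCF and carried a lentiviral short hairpin RNA (shRNA) that doxycycline switches on together with blue fluorescent protein (BFP). A control hairpin (shRen713, named for Renilla luciferase, a gene mouse cells lack) and 2 hairpins against Ogdh (shOgdh346 and shOgdh2081) were used. Cells were sorted by flow cytometry into BFP positive (hairpin induced) and BFP negative (not induced) cells. The 14 samples form 7 groups of 2: control cells at day 0, control BFP negative and BFP positive cells at days 2 and 4, and BFP positive cells with each Ogdh hairpin at day 4. Day 0 cells were untreated, and their titles do not name sorting. Comparisons with day 0 therefore combine time, doxycycline and sorting. Groups and replicate numbers were taken from the sample titles and descriptions. No label says that the replicates are separate cultures, so p-values measure the spread between these samples, which may be technical.

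The deposited values are whole-number counts of reads per gene, not normalized, with 1 column for each library. Per the labels' protocols, polyA RNA was selected, TruSeq libraries were made and single-end reads of 76 bases were sequenced. The labels' protocols name Trimmomatic, STAR, HTSeq, an RPKM matrix and a human genome build (hg19). The submitters' processing notes instead name FastQC 0.11.5, Trimmomatic 0.36, STAR 2.6.1a, featureCounts 1.6.3 and the mouse builds mm10 and GRCm38. The table holds whole counts under mouse Ensembl identifiers, and of 53274 genes that are also in the GENCODE M21 annotation of GRCm38, 51335 (96.36%) have the same coordinates there. Coordinates below are therefore given on GRCm38. The strand setting and the handling of reads that map to several places are not given in the sources used here. Antisense genes, overlapping genes and near-identical gene copies are for that reason named as uncertain. The authors also deposited a transcript length for each gene (another unit, in bases), whose source is not given in the sources used here. It was used only in a length correction.

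The table holds 53465 genes. Library totals ran from 913482 to 10271698 counts, a range of 11.2-fold. A count of 0 allows up to 3 counts (95% confidence), and such limits cover counting error only, because the reads carry no molecular identifiers. Between replicates, the chi-square per degree of freedom over genes with at least 20 counts was 1.16 to 2.71, so no pair looked like repeats of a single library. Several mitochondrial genes (mt-Co2, mt-Atp6, mt-Atp8, mt-Co3, mt-Nd4l) had 0 counts and mt-Nd3 had 1 count summed over all libraries, which is a gap in the counting and not a level.

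Genes were filtered with filterByExpr over the 7 groups, which left 10791. Counts were normalized with trimmed mean of M values (TMM) factors (0.968 to 1.013) and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3. One model held all 14 samples and the group as its only term, so that groups of 2 shared an estimate of the spread (7 residual degrees of freedom, 57.6 prior degrees of freedom, common biological coefficient of variation 5.04%). A gene was called at a Benjamini-Hochberg adjusted p under 0.05. All tests were two-sided. An exact permutation test of 2 against 2 samples cannot give a p below 0.333, so none was used. Adjusted p-values for genes are from edgeR unless another tool is named. Levels are counts-per-million (CPM) of the counts of tested genes, scaled by the TMM factors. Levels of cell type markers under Other observations and the filter of 5 CPM in 2 samples use the whole library total instead. Errors of log2 fold changes are standard errors. When tested on simulated counts for the 10791 genes, the comparison of both Ogdh hairpins with the control recovered 32%, 64%, 96% and 100% of genes changed by 1.25, 1.5, 2 and 4-fold, with 5.81% of calls false. For shOgdh346 alone these shares were 22%, 62%, 88% and 100%, with 6.21% of calls false. For control BFP positive against BFP negative cells at day 4 they were 38%, 68%, 100% and 100%, with 7.27% false. For the difference between the hairpins they were 20%, 60%, 88% and 100%, with 2.9% false. Changed genes, 50 for each fold, were drawn only from those with a mean of at least 20 counts. The shares recovered do not cover genes with fewer counts. Each comparison had a single draw, with the spread estimated from these libraries.

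The comparisons were the mean of both Ogdh hairpins, and each hairpin alone, against control BFP positive cells at day 4; the difference between the hairpins; control BFP positive against BFP negative cells at days 2 and 4 and the difference between those days; and each sorted control population against day 0. The design, the alternatives, the gene lists and the rule for naming genes were set before the data were examined. List tests were planned for the mean comparison, each hairpin, and BFP positive against BFP negative cells at days 2 and 4. They were also planned for BFP positive cells at day 4 against day 0. List tests of the other comparisons were run outside that plan. The named genes were Ogdh and, among genes called in the mean comparison and with each hairpin in the same direction at a mean of at least 5 CPM, the 10 highest and the 10 lowest by the smaller of their changes with the 2 hairpins. Clone and predicted-model names were left out. Some genes that these rules gave are not reported here. For the other comparisons the 5 highest and 5 lowest called genes at a mean of at least 5 CPM over the samples compared were named, and for each list up to 4 called members with the largest change with Ogdh knockdown. Members of lists named for the control comparisons were instead chosen after their values were seen, from those with a call in every fit that left out 1 library where there were any.

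There were 38 gene lists, covering metabolic pathways, stress responses, proliferation and blood and other cell types, with 843 members in all, of which 3 were not found in the table. The 34 lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes. List p-values were adjusted over the 34 lists. Camera was repeated with a correlation estimated from these libraries, and fry, which asks only whether the genes of a list move in 1 direction on balance, was run as well. Gene Ontology terms with 10 to 200 tested members (2166 terms, 10018 tested genes with a term) were tested in the same way after the lists had been seen. The overlap of the hairpins was set beside 20 simulations in which unchanged groups were compared with the same control libraries.

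The alternatives set in advance were relative log expression (RLE) size factors, DESeq2 1.42.0, no filter on low counts (at least 1 count), a filter of 5 CPM in 2 samples, a block for the replicate number, a block for the library number (1 to 15 against 16 to 30), fits with only the groups compared, BFP negative day 4 cells as the control, and fits without each library in turn. Where a library is left out, the remaining sample of its group is assumed to vary like the other groups. Alternatives chosen after seeing the data were an offset for a trend of each library with transcript length (loess, span 0.5), thinning of every library to 913482 counts, leaving out the shallow library of each Ogdh hairpin (shOgdh346 replicate 2 and shOgdh2081 replicate 1), and leaving Ogdh out of the list of 2-oxoacid dehydrogenase complexes. The length offset was first fitted without centring it within each library and then centred after its calls had been seen. Both forms are reported. Library numbers from 1 to 15 and from 16 to 30 each hold 1 library of every group, so no test within either set was possible.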

Results

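RNA was sequenced from the mouse AML line KL974 to learn what the cells do when Ogdh is knocked down. Ogdh encodes the E1 subunit of the 2-oxoglutarate (alpha-ketoglutarate) dehydrogenase complex, the tricarboxylic acid (TCA) cycle enzyme that turns 2-oxoglutarate into succinyl-CoA. The 14 libraries held from 913482 to 10271698 counts, and 10791 genes were tested. Depth was uneven within the Ogdh groups, with 5680900 and 1159021 counts for shOgdh346 and 913482 and 4627632 counts for shOgdh2081. In a principal component analysis the first component held 32.3% of the variance. It set the Ogdh libraries (14.4 to 27.7) apart from day 4 control libraries (-1.3 to 1), with the shallow library of each hairpin farthest out (25 and 27.7). The second component held 14.6% and its lowest scores were those of control BFP positive cells at day 2 (-12.9 and -24.1) and of shOgdh2081 replicate 1 (-12.8).

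Ogdh transcript was lower with both hairpins. It measured 247 and 267 CPM in the control BFP positive libraries at day 4 (mean 257, SD 13.6), 60.8 and 60.8 CPM with shOgdh346, and 51.5 and 52.3 CPM with shOgdh2081 (mean 51.9, SD 0.572). Over both hairpins Ogdh decreased by 78% (log2 fold change -2.19 ± 0.09, adjusted p = 1.63e-30), by 76.3% with shOgdh346 (-2.08 ± 0.11, adjusted p = 7.01e-25) and by 79.6% with shOgdh2081 (-2.30 ± 0.11, adjusted p = 9.33e-26). The hairpins were not found to differ in Ogdh level (0.22 ± 0.13, adjusted p = 0.767). In control cells Ogdh measured 302 CPM at day 0 and fell in BFP negative cells by 22% at day 2 (-0.36 ± 0.09, adjusted p = 0.00302) and by 22.2% at day 4 (-0.36 ± 0.08, adjusted p = 0.00202). In BFP positive control cells the change did not pass at day 2 (-0.23 ± 0.09, adjusted p = 0.0582) or day 4 (-0.23 ± 0.09, adjusted p = 0.0827).

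**Figure D1:**
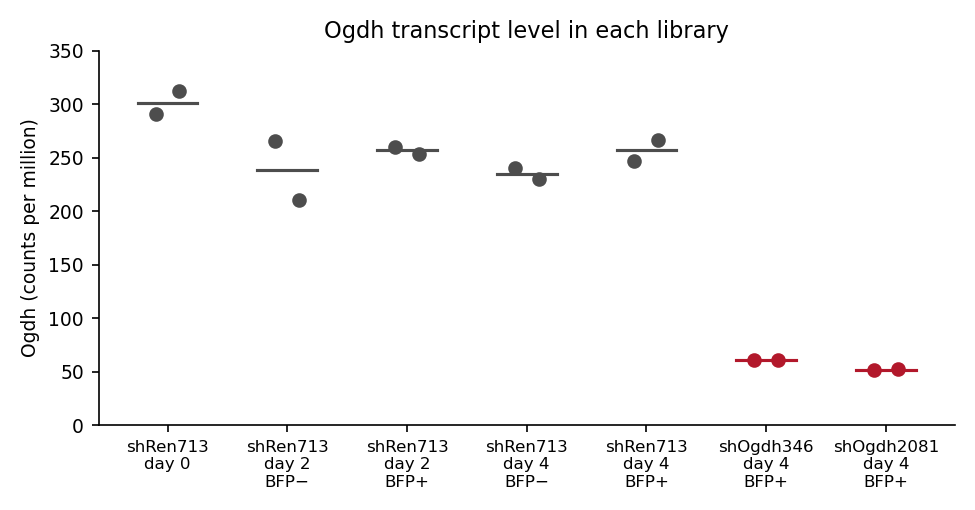
Ogdh level in each group of libraries. Points are libraries (CPM) and lines are group means.

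Single genes of growth factor signalling and the progenitor gene Gata2 were among those that fell with knockdown. Egr1 and Ier2 are immediate early genes that answer growth factor signalling, Pim1 encodes a kinase induced by cytokine signalling, and Gata2 encodes a transcription factor of blood stem cells and mast cells. Itgal encodes an integrin chain of white blood cells, and Tgfbr3 a co-receptor for TGF-beta. Egr1 fell from 200 CPM in control cells to 64.0 and 56.3 CPM with shOgdh346 and shOgdh2081 (-1.69 ± 0.10, adjusted p = 8.35e-23), and Gata2 from 163 to 76.8 and 81.8 CPM (-1.03 ± 0.09, adjusted p = 3.9e-14). Itgal (-1.24 ± 0.17), Tgfbr3 (-1.01 ± 0.16), Pim1 (-1.0 ± 0.19), Emilin2 (-0.98 ± 0.13) and Ier2 (-0.95 ± 0.11) were also lower, as were Zic2 (-0.99 ± 0.25) and Dnase1 (-0.98 ± 0.29). The calls for Zic2 and Dnase1 were lost without control BFP positive replicate 2 (-0.64 and -0.70) and without shOgdh346 replicate 1 (-0.76 and -1.05). Dnase1 also lost its call against BFP negative control cells (-0.55, adjusted p = 0.0971). By DESeq2 neither was called (Zic2 -0.99, Dnase1 -1.08, adjusted p = 0.0596 and 0.109).

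The genes that rose included stress and chromatin genes. Hmox1 encodes heme oxygenase 1, which breaks down heme and is induced by oxidative stress, and Hdac9 encodes a histone deacetylase. Hmox1 rose from 3.04 CPM in control cells to 14.6 and 12.3 CPM (2.37 ± 0.33, adjusted p = 1.21e-07). Vit (2.23 ± 0.29), Xkr9 (1.96 ± 0.32) and Hdac9 (1.90 ± 0.36) also rose. Hist1h3d (2.86 ± 0.50) and Hist1h4h (1.93 ± 0.36) are members of histone families with near-identical copies, and Hspa1b (1.81 ± 0.34), a heat shock chaperone, has the near-identical neighbor Hspa1a. Tnxb (2.93 ± 0.45) lies among overlapping genes and Il1bos (1.76 ± 0.36) is antisense to Il1b, so the source of the reads of these genes is uncertain. Of the 20 genes that the naming rule gave for knockdown, Ogdh among them, the 18 other than Zic2 and Dnase1 had a call whichever library was left out. In all, 1735 genes were called over both hairpins, 833 higher and 902 lower (670 and 1069 with the uncentred length offset), and 99 rose and 25 fell by more than 2-fold. Without control BFP positive replicate 1 the number called was 461 and without replicate 2 it was 936.

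Genes for making energy, ribosomes, DNA and nucleotides went down together. Cox5a and Atp5j encode parts of cytochrome c oxidase and of ATP synthase, Srm makes the polyamine spermidine, and Mrto4 helps assemble the large ribosomal subunit. Mcm4 and Mcm3 are parts of the replicative helicase, and Gart and Dut act in purine and thymidylate synthesis. Of 49 nuclear genes of oxidative phosphorylation, 24 fell and 25 did not pass (35 when adjusted over the list alone, median -0.23). The list was lower by camera (adjusted p = 3.63e-11), and the call was lost (adjusted p = 0.181 with an estimated correlation). Cox5a (-0.48 ± 0.12) and Atp5j (-0.47 ± 0.08) were among them, but without control BFP positive replicate 1 neither was called (-0.47 and -0.33, adjusted p = 0.0806 and 0.077). Nor was Cox5a without shOgdh2081 replicate 2 (-0.19, adjusted p = 0.37), with libraries thinned to equal depth (-0.33, adjusted p = 0.234) or by DESeq2 (-0.44, adjusted p = 0.0797). Of 29 MYC and ribosome biogenesis genes, 18 fell and 11 did not pass (21 when adjusted over the list alone, median -0.23, camera adjusted p = 3.7e-08). Srm (-0.51 ± 0.07) and Mrto4 (-0.48 ± 0.08) were lower. Of 30 DNA replication genes, 13 fell and 17 did not pass (16 when adjusted over the list alone, median -0.20, camera adjusted p = 1.84e-06). Mcm4 (-0.43 ± 0.07) and Mcm3 (-0.37 ± 0.07) were lower. Of 23 purine and pyrimidine synthesis genes, 14 fell and 9 did not pass (14 when adjusted over the list alone, median -0.25, camera adjusted p = 5.99e-06). Among them were Dctpp1 (-0.63 ± 0.12), Gart (-0.55 ± 0.07) and Dut (-0.54 ± 0.07), of which Dctpp1 lost its call with libraries thinned (-0.50, adjusted p = 0.0896). These last 3 lists kept their calls with an estimated correlation (adjusted p = 0.0297, 0.0297 and 0.037).

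Mitotic genes and genes of chromatin enzymes that use 2-oxoglutarate went up. Aurka encodes a mitotic kinase, Cenpf a kinetochore protein and Anln a protein of the cleavage furrow. Tet2 oxidizes 5-methylcytosine, and Kdm6b and Kdm3b remove methyl groups from histone H3, each with 2-oxoglutarate as a co-substrate. Of 28 mitosis genes, 10 rose and 18 did not pass (14 when adjusted over the list alone, median 0.18, camera adjusted p = 1.26e-05 and adjusted p = 0.0297 with an estimated correlation). Aurka (0.48 ± 0.09), Cenpf (0.45 ± 0.08) and Anln (0.45 ± 0.08) were higher. Of 20 dioxygenases that act on chromatin, 9 rose and 11 did not pass (13 higher and 1 lower when adjusted over the list alone, median 0.22). Camera gave a higher list (adjusted p = 5.2e-05). The call was lost (adjusted p = 0.0685 with an estimated correlation). Tet2 (0.47 ± 0.16), Kdm6b (0.43) and Kdm3b (0.40 ± 0.09) were higher. The call for Kdm3b was lost without shOgdh346 replicate 1 (0.29, adjusted p = 0.0673). That for Kdm6b was lost without control BFP positive replicate 1 (0.37, adjusted p = 0.275), replicate 2 (0.47, adjusted p = 0.0579) or shOgdh346 replicate 1 (0.31, adjusted p = 0.22), and against BFP negative control cells (0.27, adjusted p = 0.0612). The call for Tet2 was lost without control BFP positive replicate 1 (0.36, adjusted p = 0.375) or replicate 2 (0.54, adjusted p = 0.0683), shOgdh346 replicate 1 (0.52, adjusted p = 0.0596) or replicate 2 (0.44, adjusted p = 0.052), or shOgdh2081 replicate 1 (0.42, adjusted p = 0.0682). It was also lost with the length offset, centred (0.34, adjusted p = 0.121) or not (0.32, adjusted p = 0.148), with DESeq2 (0.50, adjusted p = 0.182) and with libraries thinned (0.36, adjusted p = 0.394). So was it without a filter on low counts (0.45, adjusted p = 0.0713) and without the shallow library of each hairpin (0.40, adjusted p = 0.0992). Kdm6b lost its call with DESeq2 (0.42, adjusted p = 0.165) and with libraries thinned (0.40, adjusted p = 0.269).

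**Figure D2:**
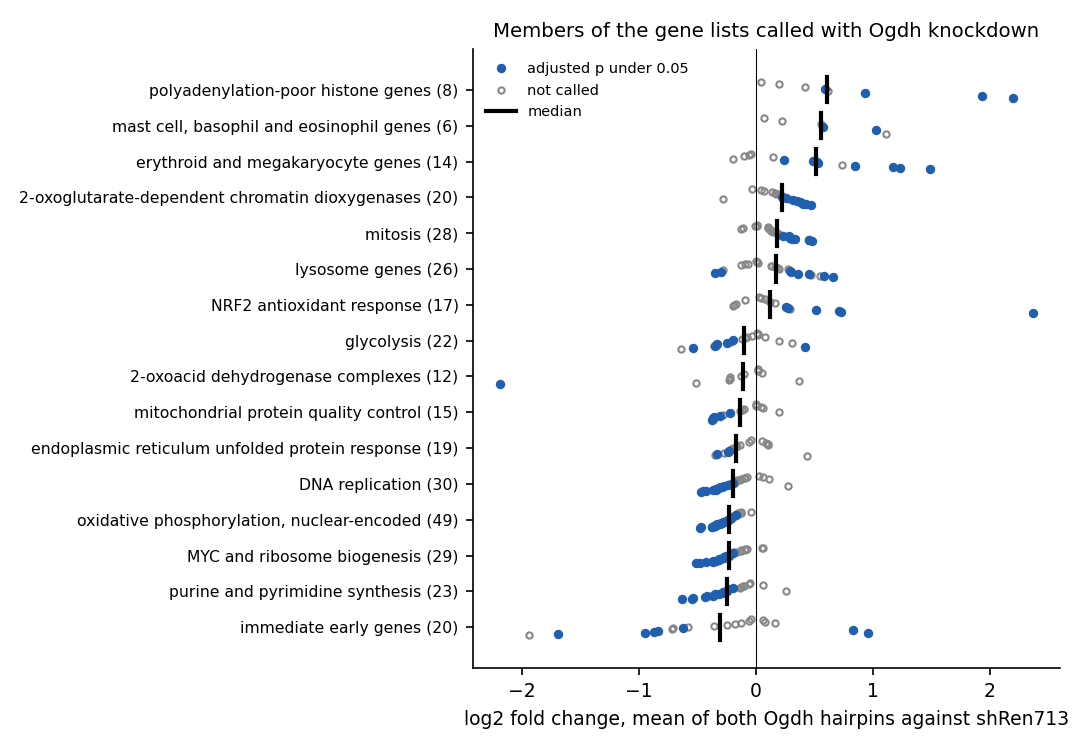
Members of gene lists in Ogdh knockdown against control cells at day 4. Blue points were called, open grey points were not, black bars are medians, and the number of tested members is in brackets.

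Erythroid, mast cell and antioxidant genes also rose. Car1 encodes carbonic anhydrase 1, made by red cell precursors, and Ms4a2 encodes the beta chain of the IgE receptor of mast cells. Nqo1, Gclc and Ftl1 (ferritin light chain) are targets of NRF2, the regulator of the antioxidant response. Of 14 erythroid and megakaryocyte genes, 8 rose and 6 did not pass (9 when adjusted over the list alone, median 0.51). By camera the list was higher (adjusted p = 5.2e-05). That call was lost (adjusted p = 0.052 with an estimated correlation, and 0.0998 with BFP negative cells as the control). Car1 (1.49 ± 0.11) and Hbb-bt (1.23 ± 0.17) were higher, the last being 1 of a pair of near-identical beta globin genes whose reads are uncertain. Against BFP negative control cells Hbb-bt did not pass (0.23, adjusted p = 0.172) while Car1 did (1.37, adjusted p = 3.06e-18). Of 6 mast cell, basophil and eosinophil genes, Ms4a2 (1.03 ± 0.11) and Il1rl1 (0.57 ± 0.08) rose and 4 did not pass (3 when adjusted over the list alone, median 0.56, camera adjusted p = 0.000904 and adjusted p = 0.0478 with an estimated correlation). Of 17 NRF2 genes, 6 rose and 11 did not pass (6 when adjusted over the list alone, median 0.12). The list was higher by camera (adjusted p = 0.00351), and the call was lost (adjusted p = 0.052 with an estimated correlation). Its called members with the largest changes were Hmox1, Ftl1 (0.73 ± 0.08), Nqo1 (0.71 ± 0.09) and Gclc (0.51 ± 0.08). Of 8 histone genes whose transcripts are poor in polyA, 4 rose and 4 did not pass (4 when adjusted over the list alone, median 0.61, camera adjusted p = 0.000175 and adjusted p = 0.0499 with an estimated correlation). The call was lost with libraries thinned to equal depth (adjusted p = 0.104). Hist1h2bc (0.93 ± 0.11) and Hist1h1c (0.59 ± 0.10) were higher, the last not called with libraries thinned (0.40, adjusted p = 0.0609).

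Weaker list calls were made for growth factor response, protein folding, glycolysis and lysosomes. Spry4 is a feedback inhibitor of growth factor signalling, Trap1 and Hspa9 encode mitochondrial chaperones, Hk2 and Ldha begin and end glycolysis, Sqstm1 encodes an autophagy receptor, and Lamp2 a protein of the lysosomal membrane. Of 20 immediate early genes, 2 rose, 5 fell and 13 did not pass (2 higher and 7 lower when adjusted over the list alone, median -0.31). Egr1, Ier2 and Spry4 (-0.87 ± 0.14) were lower. Camera gave a lower list (adjusted p = 0.0103). The call was lost (adjusted p = 0.238 with an estimated correlation, 0.0887 without control BFP positive replicate 2 and 0.0789 with libraries thinned). Of 15 mitochondrial protein quality control genes, 6 fell and 9 did not pass (6 when adjusted over the list alone, median -0.14). Trap1 (-0.38 ± 0.08) and Hspa9 (-0.37 ± 0.06) were lower. By camera the list was lower (adjusted p = 0.0239). That call was lost (adjusted p = 0.0886 with an estimated correlation, 0.0767 without shOgdh346 replicate 1, 0.133 against BFP negative control cells and 0.158 with libraries thinned). Of 22 glycolysis genes, 1 rose, 6 fell and 15 did not pass (1 higher and 7 lower when adjusted over the list alone, median -0.10). Hk2 (-0.54 ± 0.11) and Ldha (-0.35 ± 0.07) were lower, but Ldha did not pass against BFP negative control cells (-0.13, adjusted p = 0.163) and Hk2 did not with libraries thinned (-0.43, adjusted p = 0.11). The list was lower by camera (adjusted p = 0.0289), and the call was lost (adjusted p = 0.433 with an estimated correlation, 0.0706 without control BFP positive replicate 2, 0.0651 without shOgdh346 replicate 2 and 0.0763 without shOgdh2081 replicate 1). It was also lost against BFP negative control cells (0.404), with libraries thinned (0.0748), without the shallow library of each hairpin (0.134) and by fry (0.0504). Of 26 lysosome genes, 6 rose, 2 fell and 18 did not pass (9 higher and 3 lower when adjusted over the list alone, median 0.17). Sqstm1 (0.66 ± 0.08) and Lamp2 (0.45 ± 0.09) were higher. Camera gave a higher list (adjusted p = 0.0435). The call was lost (adjusted p = 0.345 with an estimated correlation, 0.154 without control BFP positive replicate 2, 0.114 without shOgdh346 replicate 1 and 0.0772 without shOgdh2081 replicate 2). Against BFP negative control cells, with libraries thinned and with the replicate block it was lost as well (0.0778, 0.0646 and 0.0526).

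Of 19 genes of the unfolded protein response of the endoplasmic reticulum, 3 fell and 16 did not pass (5 when adjusted over the list alone, median -0.17). These were Manf (-0.33), a secreted survival factor, and the chaperone genes Dnajb11 (-0.24) and Hspa5 (-0.23). By camera the list was lower (adjusted p = 0.0308). That call was lost (adjusted p = 0.247 with an estimated correlation, 0.0798 without control BFP positive replicate 2, 0.0548 without shOgdh346 replicate 1, 0.0627 without shOgdh2081 replicate 2, 0.0922 against BFP negative control cells and 0.104 with libraries thinned). Nor did the 3 genes pass against BFP negative control cells (Manf -0.22, Dnajb11 -0.21, Hspa5 -0.16, adjusted p = 0.0773, 0.0514 and 0.0565) or with libraries thinned (-0.21, -0.24 and -0.24, adjusted p = 0.454, 0.248 and 0.0572). DESeq2 did not call Manf (-0.30, adjusted p = 0.191) or Dnajb11 (-0.25, adjusted p = 0.186). Without control BFP positive replicate 1 the 3 genes were not called (Manf -0.15, Dnajb11 -0.36, Hspa5 -0.22, adjusted p = 0.617, 0.0605 and 0.167), nor without shOgdh346 replicate 1 (-0.27, -0.27 and -0.21, adjusted p = 0.15, 0.0918 and 0.0633). Without control BFP positive replicate 2 Dnajb11 (-0.14, adjusted p = 0.476) and Hspa5 (-0.24, adjusted p = 0.0751) were not called. Without shOgdh2081 replicate 2 Manf (-0.25, adjusted p = 0.202) and Dnajb11 (-0.30, adjusted p = 0.0666) were not. Dnajb11 also lost its call without shOgdh346 replicate 2 (-0.24, adjusted p = 0.0773) and shOgdh2081 replicate 1 (-0.22, adjusted p = 0.0948), both of these together (-0.21, adjusted p = 0.15), a filter on low counts (-0.26, adjusted p = 0.0762) or with the length offset (-0.22, adjusted p = 0.0671). Of 12 genes of the 2-oxoacid dehydrogenase complexes, Ogdh fell and 11 did not pass (1 when adjusted over the list alone, median -0.11). Camera called the list lower (adjusted p = 0.0461), but Ogdh is the gene that the hairpins target. Without Ogdh the other 11 were not called (median -0.10, adjusted p = 0.251), so the list is not counted as a change beyond the knockdown. With Ogdh in it the call was lost as well (adjusted p = 0.28 with an estimated correlation, 0.12 without control BFP positive replicate 2, 0.0708 without shOgdh346 replicate 1 and 0.0763 without shOgdh2081 replicate 1). It was also lost against BFP negative control cells (0.108), with libraries thinned (0.158), without the shallow library of each hairpin (0.104) and with the length offset, centred (0.0531) or not (0.0537).

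Camera did not call 18 lists, though single genes moved in most of them. The ATF4 and amino acid stress list held 2 higher and 8 lower of 34 (4 and 10 when adjusted over the list alone, adjusted p = 0.0687). Phgdh (-0.73 ± 0.11), the first enzyme of serine synthesis, fell and Slc6a9 (0.74 ± 0.14), a glycine transporter gene, rose. Of 20 TCA cycle genes, 4 fell (4 when adjusted over the list alone, adjusted p = 0.0797), each by at most 0.29 and none with a call in every fit that left out 1 library. Among sterol genes 1 rose and 2 fell of 25 (1 and 1 when adjusted over the list alone, adjusted p = 0.0995). Among heme synthesis genes Uros (0.74 ± 0.14) was 1 of 2 higher of 12 (2 when adjusted over the list alone, adjusted p = 0.0996). Among p53 targets Perp (-0.71 ± 0.13) and Rps27l (-0.53 ± 0.09) were 2 of 3 lower, with 2 higher, of 18 (3 and 3 when adjusted over the list alone, adjusted p = 0.0996). For glutamine metabolism 1 rose and 5 fell of 19 (2 and 5 when adjusted over the list alone, adjusted p = 0.203). For fatty acid synthesis 1 rose and 6 fell of 19 (2 and 7, adjusted p = 0.417), including Scd2 (-0.65 ± 0.07), a desaturase. Tnfaip3 (0.59 ± 0.07), an inhibitor of NF-kB, was the 1 called of 7 inflammatory genes (2 when adjusted over the list alone, adjusted p = 0.239). Vim (-0.62 ± 0.07), an intermediate filament gene, was 1 of 3 lower of 7 stromal genes (3 when adjusted over the list alone, adjusted p = 0.299). That list had a median of 0.07, a mean of -0.19 and a lower direction in the test.

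Stem and progenitor genes went both ways, with 3 higher and 3 lower of 14 (3 and 5 when adjusted over the list alone, adjusted p = 0.473), Gata2 among the lower. Heat shock genes gave 2 higher and 2 lower of 13 (2 and 2, adjusted p = 0.622) and HIF targets 5 higher and 1 lower of 21 (5 and 1, adjusted p = 0.7). The HIF list had a median of -0.02, a mean of 0.09 and a higher direction in the test. Of 15 interferon genes 1 rose by edgeR but not when adjusted over the list alone (adjusted p = 0.473). Of 5 monocyte genes 1 fell (1 when adjusted over the list alone, adjusted p = 0.622). Of 7 pentose phosphate genes 2 fell (2, adjusted p = 0.979, median 0.11, mean 0.01, lower in the test). Of 7 mitochondrially encoded mRNAs, mt-Co1 rose (0.34 ± 0.07) and 1 fell (1 and 2 when adjusted over the list alone, adjusted p = 0.916, median -0.05, mean 0.01, higher in the test). None of the 16 apoptosis regulators passed in edgeR (unadjusted p < 0.05 for 1 higher and 2 lower, 0 by DESeq2, adjusted p = 0.657 for the list, median 0.01, mean -0.03, lower in the test). None of the 5 dendritic cell genes did either in edgeR (unadjusted p < 0.05 for 1 lower, 0 by DESeq2, adjusted p = 0.794, median -0.01, mean 0.05, lower in the test).

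Lists with under 5 tested members were read gene by gene. Ctsc, which encodes the protease that activates granule enzymes, fell (-0.69 ± 0.13, adjusted p = 5.01e-05, but -0.47 and adjusted p = 0.15 with libraries thinned), while its fellow primary granule genes Cst7 (-0.39, adjusted p = 0.0821) and Srgn (-0.06, adjusted p = 0.61) did not pass. The neutrophil genes Anxa1 (-0.30, adjusted p = 0.0783) and Il1b (-0.28, adjusted p = 0.664) and the lymphoid genes Tcf7 (-0.70, adjusted p = 0.423) and Gata3 (-0.28, adjusted p = 0.348) did not pass. Of the genes named in the cell genotype, Nf1, an inhibitor of RAS that a hairpin silences in this line, rose from 56.4 CPM in control cells to 110 and 107 CPM with shOgdh346 and shOgdh2081 (0.91 ± 0.11, adjusted p = 1.48e-09). Kmt2c (0.14 ± 0.09, adjusted p = 0.308) and Trp53 (-0.16 ± 0.08, adjusted p = 0.186) did not pass.

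The hairpins gave similar changes. Car1, Hmox1 and Nf1 rose and Egr1 and Gata2 fell with each of them. With shOgdh346 1206 genes were called (602 higher, 604 lower) and with shOgdh2081 1247 (650 higher, 597 lower), and 714 of these were shared in direction (364 higher, 350 lower). That is 59.2% and 57.3% of the calls. With a transcript-length offset that was not centred, shOgdh346 gave 547 higher and 778 lower, shOgdh2081 gave 495 higher and 712 lower, and the shared genes were 309 higher and 453 lower. No gene was called in opposite directions in edgeR (0 also at unadjusted p < 0.05, where 1708 genes went the same way, and 0 by DESeq2). Independent calls would overlap in 36.3 higher and 33.4 lower genes, while simulated unchanged groups set against the same control libraries shared at most 0 calls in 20 draws (the highest number called was 1). Fold changes correlated at r = 0.771. Between simulated unchanged groups the shared control alone gave r = 0.525. The covariance was 0.114, against 0.0318 in the simulations. With no shared library, shOgdh346 was set against BFP positive and shOgdh2081 against BFP negative control cells. Then 644 genes were called with both hairpins, and 623 the other way round. Both control populations carried the same control hairpin, and no uninduced Ogdh hairpin cells were sequenced. Differences between the transduced cells from before induction therefore cannot be told apart from knockdown. The number shared was 204 without control BFP positive replicate 1, 404 without replicate 2, 293 without shOgdh346 replicate 1 and 260 without shOgdh2081 replicate 2. For shOgdh346 alone the number called was 369, 627, 381 and 736 without control replicates 1 and 2 and shOgdh346 replicates 1 and 2. For shOgdh2081 alone it was 337, 732, 732 and 469 without control replicates 1 and 2 and shOgdh2081 replicates 1 and 2. Camera called 8 lists higher and 9 lower with shOgdh346, and 6 higher and 7 lower with shOgdh2081. Glutamine metabolism and heme synthesis were called with shOgdh346 but not over both hairpins. For the former 3 of 19 genes fell (4 when adjusted over the list alone, adjusted p = 0.0336 and adjusted p = 0.221 with an estimated correlation). For the latter 3 of 12 rose (3 when adjusted over the list alone, adjusted p = 0.0448 and adjusted p = 0.249 with an estimated correlation).

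**Figure D3:**
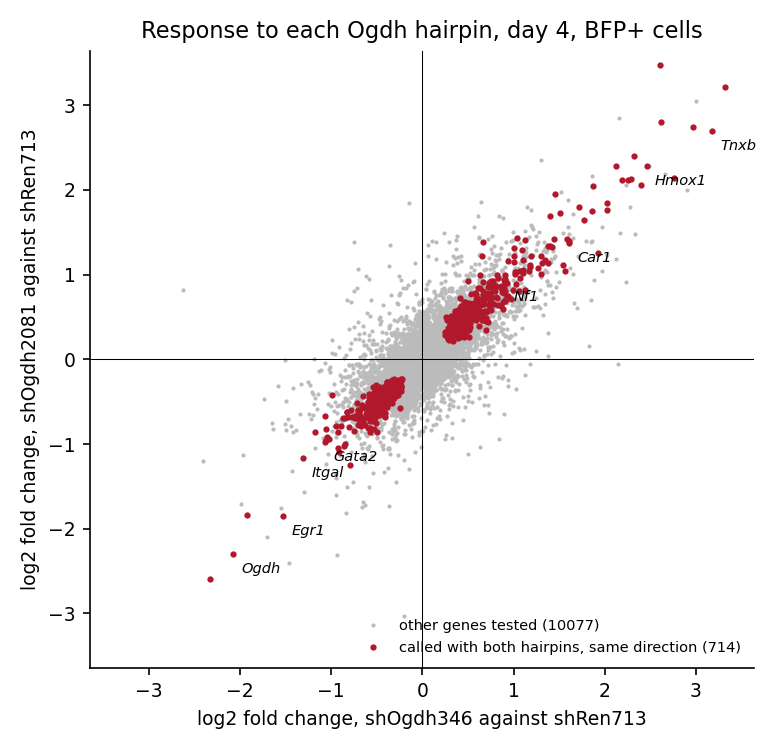
Log2 fold changes of the 10791 tested genes with shOgdh346 and shOgdh2081 against control BFP positive cells at day 4, which both share. Red points are the 714 genes called with both hairpins in the same direction, and grey points the others.

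Few genes differed between the hairpins. Pi4k2b, a phosphatidylinositol kinase gene, was higher with shOgdh346 than with shOgdh2081 (0.67 ± 0.11, adjusted p = 0.000568), and Sh3bgrl, which encodes a small adaptor protein, was lower (-0.71 ± 0.12, adjusted p = 0.000568). Lars2, which encodes the mitochondrial leucyl-tRNA synthetase (-0.79 ± 0.16), mt-Rnr1, the small ribosomal RNA of mitochondria (-0.55 ± 0.10), and Ppp1cb, a phosphatase subunit gene (-0.43 ± 0.09), were lower with shOgdh346. Rps21, a ribosomal protein gene (0.37 ± 0.08), was higher. The largest differences were those of Gm15564 (-1.29 ± 0.24), Mir6236 (-1.25 ± 0.25) and Gm26917 (-0.80 ± 0.17), lower with shOgdh346. Gm15564 and Gm26917 have predicted-model names and were named after their values were seen. These loci and Lars2 hold sequence that resembles ribosomal RNA, so it is uncertain whether their reads came from these genes. In all 9 genes were called, 2 higher and 7 lower, with 786 at unadjusted p < 0.05 and 1 by DESeq2. Without shOgdh346 replicate 1 edgeR called 0 (602 at unadjusted p < 0.05) and without shOgdh2081 replicate 2 it called 24. Without shOgdh346 replicate 1 none of the 9 was called. Their values then were Pi4k2b 0.73, Sh3bgrl -0.72, Lars2 -0.34, mt-Rnr1 -0.37, Ppp1cb -0.49 and Rps21 0.39 (adjusted p = 0.216, 0.245, 0.928, 0.902, 0.673 and 0.673). Those of Gm15564, Mir6236 and Gm26917 were -0.60, -0.89 and -0.72 (adjusted p = 0.924, 0.902 and 0.876). Without shOgdh346 replicate 2 the calls for Ppp1cb (-0.40, adjusted p = 0.21) and Rps21 (0.36, adjusted p = 0.21) were lost. Without shOgdh2081 replicate 1 those for Lars2 (-0.66, adjusted p = 0.325), Sh3bgrl (-0.49, adjusted p = 0.107), Ppp1cb (-0.34, adjusted p = 0.562) and Rps21 (0.34, adjusted p = 0.508) were lost. Leaving out shOgdh2081 replicate 2 removed those for mt-Rnr1 (-0.47, adjusted p = 0.264), Rps21 (0.44, adjusted p = 0.0921), Gm15564 (-1.43, adjusted p = 0.0935), Mir6236 (adjusted p = 0.243) and Gm26917 (-0.57, adjusted p = 0.561). With libraries thinned Lars2 (-0.63, adjusted p = 0.137) and mt-Rnr1 (-0.37, adjusted p = 0.519) were not called, nor with the length offset Rps21 (0.30, adjusted p = 0.094) and Ppp1cb (-0.38, adjusted p = 0.0697). The 1 gene that DESeq2 called was Pi4k2b. Oxidative phosphorylation genes were called higher with shOgdh346 than with shOgdh2081 (median 0.10, camera adjusted p = 0.000287), but the call was lost (adjusted p = 0.867 with an estimated correlation, and 0.0702 without shOgdh346 replicate 1). None of its 49 members passed in edgeR (6 higher at unadjusted p < 0.05, 0 by DESeq2, 1 higher when adjusted over the list alone).

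In control cells, induction of the hairpin vector was accompanied at day 2 by an amino acid stress response. Cth and Psat1 make cysteine and serine, Slc7a5 imports large neutral amino acids, and all are targets of ATF4, as is Chac1, which degrades glutathione. Yap1 encodes a transcriptional coactivator of the Hippo pathway, Dock10 an activator of small GTPases, Ass1 an enzyme of arginine synthesis, Cdh19 a cadherin, and Cpne5 a calcium-dependent membrane-binding protein. In BFP positive against BFP negative cells, 17 of 34 ATF4 and amino acid stress genes rose and 17 did not pass (23 when adjusted over the list alone, median 0.30, camera adjusted p = 1.04e-11 and adjusted p = 0.0355 with an estimated correlation). Cth (1.02 ± 0.14), Slc7a5 (0.46) and Psat1 (0.42) were higher. Chac1 (2.06 ± 0.45), Espnl (1.88 ± 0.41), Yap1 (1.56 ± 0.24), Dock10 (1.35 ± 0.16) and Hoxc5 (1.29 ± 0.26) were the highest called genes at a mean of at least 5 CPM. Plekhh2 (-2.97 ± 0.47), Cpne5 (-2.65 ± 0.32), Ctla2a (-2.57 ± 0.40), Cdh19 (-2.56 ± 0.30) and Ass1 (-2.43 ± 0.40) were the lowest at that level. Without BFP positive day 2 replicate 1 the calls for Chac1 (1.58), Espnl, Hoxc5 (0.83) and Ass1 (-1.74) were lost. Leaving out BFP negative day 2 replicate 2 removed those for Chac1 (1.89) and Hoxc5 (1.01). With libraries thinned Hoxc5 (1.10, adjusted p = 0.206) and Ass1 (-1.85, adjusted p = 0.144) were not called, and by DESeq2 Chac1 (1.99, adjusted p = 0.16) and Espnl (adjusted p = 0.0865) were not. In all 672 genes were called, 324 higher and 348 lower (502 and 302 with the uncentred length offset). The number was 434 without BFP negative replicate 1 and 233 without BFP positive replicate 1. By more than 2-fold 28 rose and 120 fell.

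Interferon, sterol and erythroid genes also differed with induction at day 2. Xaf1 and Trim30a are interferon-induced genes. Of 15 interferon genes, 4 fell and 11 did not pass (5 when adjusted over the list alone, median -0.27, camera adjusted p = 0.00038 and adjusted p = 0.0355 with an estimated correlation). Trim30a (-1.89 ± 0.48) and Xaf1 (-1.84 ± 0.42) were the lowest of them, but no member was called in every fit that left out 1 library. Of 25 sterol genes, 2 rose and 1 fell (5 and 1 when adjusted over the list alone, median 0.21, camera adjusted p = 0.000515 and adjusted p = 0.0355 with an estimated correlation). Of 14 erythroid and megakaryocyte genes, 1 rose and 6 fell (1 and 9 when adjusted over the list alone, median -0.50, camera adjusted p = 0.00038), a call that was lost (adjusted p = 0.134 with an estimated correlation). Hbb-bt (-1.08) and Hba-a1 (-0.69), of families with near-identical copies, fell. Of 7 mitochondrially encoded mRNAs, 6 rose, with mt-Nd5 (0.40) and mt-Nd4 (0.39) among them. When adjusted over the list alone it was also 6 (median 0.37, camera adjusted p = 0.00038), and the call was lost (adjusted p = 0.345 with an estimated correlation).

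Another 5 lists were called at day 2 with no call that held in every setting. Of 26 lysosome genes 2 fell (7 when adjusted over the list alone, adjusted p = 0.00509 and adjusted p = 0.298 with an estimated correlation, and 0.093 without BFP positive replicate 2). Of 8 polyA-poor histone genes 2 rose (adjusted p = 0.0116 and adjusted p = 0.22 with an estimated correlation, and 0.0661, 0.069, 0.117 and 0.106 without BFP negative replicates 1 and 2 and BFP positive replicates 1 and 2). Of 23 purine and pyrimidine synthesis genes 2 rose (3 when adjusted over the list alone, adjusted p = 0.0382 and adjusted p = 0.298 with an estimated correlation, and 0.0661 and 0.347 without BFP negative and BFP positive replicate 1). Of 22 glycolysis genes 5 rose and 1 fell (7 and 1 when adjusted over the list alone, adjusted p = 0.0447 and adjusted p = 0.528 with an estimated correlation, and 0.0661, 0.134 and 0.369 without BFP negative replicates 1 and 2 and BFP positive replicate 1). Ldha (0.64) and Aldoa (0.56) rose and Eno2 (-2.25) fell. Of 21 HIF targets 4 rose and 1 fell (5 and 1 when adjusted over the list alone, adjusted p = 0.0447 and adjusted p = 0.298 with an estimated correlation, and 0.0657, 0.0745, 0.198 and 0.0577 without BFP negative replicates 1 and 2 and BFP positive replicates 1 and 2). The fallen gene was Egln1 (-2.20), which encodes the oxygen sensor that marks HIF for destruction.

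By day 4 few genes separated the BFP positive from the BFP negative control cells. Rapgef4 encodes an exchange factor activated by cyclic AMP, and Il9r the receptor of interleukin 9. Rapgef4 (1.00 ± 0.12), Il9r (0.77 ± 0.12), Mettl9 (0.65 ± 0.14) and Egr1 (0.42 ± 0.09) were higher. The beta globin genes Hbb-bt (-1.0 ± 0.17) and Hbb-bs (-0.73 ± 0.11), Slc26a1 (-0.50 ± 0.11) and Sec11c (-0.42 ± 0.09) were lower. These 8 were all the genes called (498 at unadjusted p < 0.05, and 3 by DESeq2), and Rapgef4 and Hbb-bs had a call whichever library was left out. With libraries thinned Rapgef4 lost its call (0.76, adjusted p = 0.464), and so did Mettl9, Egr1, Hbb-bt, Slc26a1 and Sec11c (adjusted p = 0.97, 0.984, 0.743, 0.97 and 0.285). The 3 genes that DESeq2 called were Rapgef4, Il9r and Hbb-bs. Without BFP positive replicate 1 the number called was 3, without BFP positive replicate 2 it was 3, and without BFP negative replicate 2 it was 16. The calls lost without BFP positive replicate 1 were Mettl9 (0.44, adjusted p = 1), Egr1 (0.51, adjusted p = 0.218), Hbb-bt (-1.05, adjusted p = 0.218), Slc26a1 (-0.44, adjusted p = 1) and Sec11c (-0.49, adjusted p = 0.267). Without BFP positive replicate 2 they were Il9r (0.68, adjusted p = 0.0578), Egr1 (0.33, adjusted p = 1), Hbb-bt (-0.97, adjusted p = 0.0635), Slc26a1 (-0.54, adjusted p = 0.193) and Sec11c (-0.37, adjusted p = 0.776). Without BFP negative replicate 1 they were Mettl9 (0.53, adjusted p = 0.241) and Slc26a1 (-0.50, adjusted p = 0.0946). Without BFP negative replicate 2 they were Egr1 (0.28, adjusted p = 0.568), Slc26a1 (-0.49, adjusted p = 0.227) and Sec11c (-0.34, adjusted p = 0.41). Camera called 4 lists higher and 2 lower, each lost with an estimated correlation and without at least 1 library. Of 14 erythroid and megakaryocyte genes 2 fell (4 when adjusted over the list alone, median -0.08, adjusted p = 7.9e-05 and adjusted p = 0.139 with an estimated correlation, and 0.116 without BFP positive replicate 1). None of 6 mast cell genes passed in edgeR (2 higher at unadjusted p < 0.05, 0 by DESeq2, 2 when adjusted over the list alone, median 0.36, adjusted p = 0.00183 and adjusted p = 0.139 with an estimated correlation, and 0.116 and 0.0522 without BFP positive replicate 1 and BFP negative replicate 2).

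The effect of induction differed between day 2 and day 4 for 71 genes, which were all called at day 2. Their day 4 minus day 2 difference had the opposite sign to the day 2 effect. Since the day 2 effect is subtracted in it, that sign does not show a reversal at day 4. Afap1l1, an actin-binding protein gene, had a day 4 minus day 2 difference of 3.81 ± 0.82 (-3.73 at day 2 and 0.07 at day 4). It, Ctla2a (2.61), Cpne5 (2.55), Hmgn3 (2.41) and Arfgef3 (2.35) were lower than in BFP negative cells at day 2, not at day 4. Yap1 (-1.86, with 1.56 at day 2 and -0.30 at day 4), Pparg (-1.47), a lipid-sensing nuclear receptor gene, Dock10 (-1.40), Bcl7a (-1.38) and Pcsk6 (-1.23) were high at day 2 and not at day 4. Of the 71 genes, 45 had a positive difference and 26 a negative one (45 and 40 with the uncentred length offset). At unadjusted p < 0.05 there were 1057. The number called was 30 called without BFP positive day 2 replicate 1, and 31 and 46 without BFP positive day 4 replicates 1 and 2. The difference for Cpne5, Yap1 and Dock10 was called whichever library was left out, but with libraries thinned Yap1 (-1.95, adjusted p = 0.262) and Dock10 (-1.43, adjusted p = 0.0709) lost their calls. So did Pparg (-1.09, adjusted p = 0.772), Bcl7a (-1.45, adjusted p = 0.356) and Pcsk6 (-0.97, adjusted p = 0.746). By DESeq2 Afap1l1, Ctla2a, Arfgef3, Pparg, Bcl7a and Pcsk6 were not called (adjusted p = 0.31, 0.234, 0.556, 0.836, 0.106 and 0.504). Without BFP positive day 2 replicate 1 the calls lost were Afap1l1 (7.59), Ctla2a (2.36), Arfgef3 (3.21), Pparg (-0.84) and Pcsk6 (-1.28). Without BFP positive day 4 replicate 1 they were Ctla2a (2.22), Hmgn3 (1.94), Arfgef3 (2.79), Pparg (-1.35), Bcl7a (-1.14) and Pcsk6 (-1.23). Without BFP negative day 2 replicate 2 they were Ctla2a (2.17, adjusted p = 0.062) and Pparg (-1.08, adjusted p = 0.198). Arfgef3 also lost its call without BFP negative day 2 replicate 1 (2.11, adjusted p = 0.139), BFP positive day 2 replicate 2 (2.04, adjusted p = 0.154), BFP positive day 4 replicate 2 (1.94, adjusted p = 0.42) and BFP negative day 4 replicates 1 and 2 (2.34 and 2.36, adjusted p = 0.0526 and 0.132). Among lists, ATF4 and amino acid stress genes had a negative difference (1 of 34 called, 8 when adjusted over the list alone, camera adjusted p = 9.84e-09), but the call was lost (adjusted p = 0.0788 with an estimated correlation).

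Sterol synthesis and HIF target genes were higher in control cells at day 2 than at day 0, whether or not BFP was on. Day 0 cells were untreated and not labelled as sorted. Time, doxycycline and sorting thus cannot be told apart in this or the following comparisons with day 0. Sqle and Msmo1 encode enzymes of cholesterol synthesis, and Acat2 makes its precursor acetoacetyl-CoA. Vegfa encodes an angiogenic growth factor and Pdk1 a kinase that inhibits pyruvate dehydrogenase. Bnip3 encodes a mitophagy receptor and Slc16a3 the lactate exporter MCT4. All of these genes respond to HIF. In BFP negative cells 11 of 25 sterol genes rose and 14 did not pass (17 when adjusted over the list alone, median 0.46, camera adjusted p = 3.07e-11 and adjusted p = 0.00319 with an estimated correlation). Msmo1 (0.74), Acat2 (0.69) and Sqle (0.60) were higher. With BFP on, 19 rose and 1 fell (20 and 1 when adjusted over the list alone, median 0.65, camera adjusted p = 5.82e-12 and adjusted p = 0.00262 with an estimated correlation). Of 21 HIF targets, 11 rose in BFP negative cells (13 when adjusted over the list alone, median 0.64, camera adjusted p = 4.81e-11 and adjusted p = 0.00803 with an estimated correlation). Vegfa (2.36 ± 0.28), Ddit4 (1.63), P4ha1 (1.41) and Pdk1 (0.86) were higher. In BFP positive cells 11 rose and 1 fell (14 and 1 when adjusted over the list alone, median 0.87, camera adjusted p = 1.4e-09 and adjusted p = 0.0124 with an estimated correlation). Vegfa (2.72) and Bnip3 (2.67) were higher. Of 22 glycolysis genes 11 rose in BFP negative cells (11 when adjusted over the list alone, median 0.32, camera adjusted p = 1.92e-06). In BFP positive cells 13 rose and 1 fell (15 and 2 when adjusted over the list alone, median 0.41, camera adjusted p = 4.52e-07). Pfkl (0.59 and 0.62) and Tpi1 (0.55 and 0.67) rose in each. Both glycolysis calls were lost (adjusted p = 0.287 and 0.248 with an estimated correlation). Of 34 ATF4 and amino acid stress genes 21 rose in BFP positive cells (23 when adjusted over the list alone, median 0.37, camera adjusted p = 2.17e-09), a call that was lost (adjusted p = 0.0624 with an estimated correlation). Ddit4 (2.25) and Cth (1.42) were higher.

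Antioxidant genes fell and mitochondrial transcripts rose over the same days. Txnrd1 and Srxn1 encode thioredoxin reductase 1 and sulfiredoxin, NRF2 targets that restore oxidized proteins. Of 17 NRF2 genes, 8 fell in BFP negative cells at day 2 and 9 did not pass (1 higher and 10 lower when adjusted over the list alone, median -0.31, camera adjusted p = 0.000135 and adjusted p = 0.0377 with an estimated correlation). Txnrd1 (-0.58) and Srxn1 (-0.58) were lower. Of the same list 7 fell in BFP positive cells (1 higher and 7 lower when adjusted over the list alone, camera adjusted p = 0.00788), a call that was lost (adjusted p = 0.117 with an estimated correlation). All 7 mitochondrially encoded mRNAs rose against day 0 in each population and day, with medians of 0.49 and 0.85 at day 2 and 0.55 and 0.68 at day 4 in BFP negative and BFP positive cells (7 of 7 when adjusted over the list alone). Camera called each (adjusted p = 1.24e-07, 3.83e-09, 1.47e-09 and 8.87e-11), and each call was lost (adjusted p = 0.264, 0.193, 0.14 and 0.12 with an estimated correlation). Mitochondrial genes held 1.556% and 1.629% of counts at day 0 and 2.289% to 3.087% in the other libraries. Against day 0, camera called 5 lists higher and 2 lower in BFP negative cells at day 2 and 3 higher and 6 lower at day 4. In BFP positive cells it called 8 higher and 2 lower at day 2 and 4 higher and 5 lower at day 4. With an estimated correlation, sterol, HIF and NRF2 genes kept the call in BFP negative cells at day 2. Sterol and HIF genes kept it in BFP positive cells at day 2. MYC and ribosome biogenesis genes kept it in BFP negative cells at day 4. No other list did. These list tests were run outside the design set beforehand.

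The highest and lowest called genes against day 0 at day 2 are given here among those at a mean of at least 5 CPM. In BFP negative cells Cxxc5 (3.14 ± 0.49), Slc16a3 (2.94 ± 0.36), Itm2a (2.86 ± 0.39), Vegfa and Cdh19 (2.25 ± 0.27) rose most. The chromatin gene H2afy (-2.05 ± 0.41), Panx3 (-1.56), B4galt5 (-1.45), Plcd4 (-1.45) and Arid5a (-1.38) fell most. Without BFP negative day 2 replicate 2 the calls for H2afy (-1.38, adjusted p = 0.133), Panx3 (-1.33, adjusted p = 0.0918), B4galt5 (-1.54, adjusted p = 0.138), Plcd4 (-0.70, adjusted p = 0.424) and Arid5a (-1.24, adjusted p = 0.165) were lost. So were those for B4galt5 without day 0 replicate 1 (-1.22, adjusted p = 0.18) and for Plcd4 (-1.16, adjusted p = 0.133) and Arid5a (-1.35, adjusted p = 0.0639) without day 0 replicate 2. With libraries thinned Panx3 (-1.22, adjusted p = 0.304), Plcd4 (-1.62, adjusted p = 0.125) and Arid5a (-1.54, adjusted p = 0.273) were not called. By DESeq2 B4galt5, Plcd4 and Arid5a were not (adjusted p = 0.185, 0.128 and 0.125). In all 1112 genes were called, 575 higher and 537 lower (494 and 706 with the uncentred length offset). The number called was 438 and 429 without day 0 replicates 1 and 2 and 330 without BFP negative replicate 2. In BFP positive cells 1928 genes were called (982 higher, 946 lower, 1069 and 911 with the uncentred length offset), 1033 and 1110 without day 0 replicates 1 and 2 and 860 without BFP positive replicate 1. Slitrk5 (3.73 ± 0.58), Slc16a3 (3.12), Chac1 (2.84), Vegfa and Bnip3 rose most. C1s1 (-2.36 ± 0.21), Plcd4 (-2.32), Gp5 (-2.18), Traf3 (-2.14) and Cpne5 (-2.00) fell most. The call for Chac1 was lost without BFP positive day 2 replicate 1 (2.35, adjusted p = 0.0512).

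At day 4 the control cells had lower ribosome biogenesis and replication genes than at day 0 and higher Egr1. Rrp12, Bop1 and Mybbp1a act in making ribosomes, Txnip binds thioredoxin and restrains glucose uptake, and Lig1 joins newly made DNA. Egr1 rose in BFP negative (2.55 ± 0.13, adjusted p = 1.32e-24) and BFP positive cells (2.97 ± 0.13, adjusted p = 7.65e-28). Of 29 MYC and ribosome biogenesis genes 11 fell in BFP negative cells and 18 did not pass (13 when adjusted over the list alone, median -0.17, camera adjusted p = 2.02e-08 and adjusted p = 0.0302 with an estimated correlation). Rrp12 (-0.58), Mybbp1a (-0.49) and Bop1 (-0.43) were lower. Of the same list 10 fell in BFP positive cells (1 higher and 11 lower when adjusted over the list alone, median -0.12, camera adjusted p = 5.52e-05), a call that was lost (adjusted p = 0.0574 with an estimated correlation). Of 30 DNA replication genes 1 rose and 9 fell in BFP negative cells (1 and 10 when adjusted over the list alone, median -0.15, camera adjusted p = 0.000126). In BFP positive cells 9 fell (11 when adjusted over the list alone, median -0.17, camera adjusted p = 1.56e-05). Lig1 fell in each (-0.39 and -0.42). Both calls were lost (adjusted p = 0.0895 and 0.0574 with an estimated correlation). Glycolysis genes, higher at day 2, were not higher at day 4 in either population. In BFP negative cells 0 rose and 5 fell of 22 in edgeR (2 higher at unadjusted p < 0.05 and 0 by DESeq2, 2 higher and 8 lower when adjusted over the list alone, median -0.16, camera adjusted p = 0.0301). That lower call was lost (adjusted p = 0.609 with an estimated correlation, 0.0981 and 0.0797 without day 0 replicates 1 and 2 and 0.296 without BFP negative day 4 replicate 2). With BFP on, 3 fell (2 higher and 3 lower when adjusted over the list alone, median -0.06), and camera did not call the list (adjusted p = 0.664). Also with BFP on, Ms4a2 (1.59 ± 0.17) and Il1rl1 (0.60) were the 2 higher of 6 mast cell genes (2 when adjusted over the list alone, median 0.49, camera adjusted p = 0.00145), a call that was lost (adjusted p = 0.0574 with an estimated correlation).

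Other genes that changed most in BFP negative cells at day 4, among those at a mean of at least 5 CPM, were Slc6a19 (1.82 ± 0.23), Txnip (1.5 ± 0.09), Dcn (1.30) and Vegfa (1.29) on the higher side. Those on the lower side were Mir6236 (-1.40 ± 0.20), Dusp14 (-1.12), Gstt1 (-1.07 ± 0.13), Snrpf (-1.06) and Lars2 (-0.91), of which the first and last resemble ribosomal RNA and are uncertain. Without day 0 replicate 1 the calls for Dcn (1.23, adjusted p = 0.0637), Vegfa (1.28, adjusted p = 0.0672) and Snrpf (-1.13, adjusted p = 0.0603) were lost. Leaving out day 0 replicate 2 removed those for Vegfa (1.29, adjusted p = 0.0656), Dusp14 (-0.85, adjusted p = 0.364) and Snrpf (-1.0, adjusted p = 0.117). Without BFP negative day 4 replicate 1 Dusp14 (-0.94, adjusted p = 0.0707) was not called, and without replicate 2 Dcn (1.18, adjusted p = 0.0741) and Snrpf (-1.03, adjusted p = 0.148) were not. With libraries thinned Dcn and Vegfa were not called (adjusted p = 0.124 and 0.127). By DESeq2 Dcn, Vegfa, Mir6236, Dusp14, Snrpf and Lars2 were not (adjusted p = 0.0957, 0.076, 0.295, 0.359, 0.285 and 0.241). In all 866 genes were called, 414 higher and 452 lower (363 and 710 with the uncentred length offset). The number was 303 and 222 without day 0 replicates 1 and 2 and 222 without BFP negative day 4 replicate 2. In BFP positive cells 767 were called, 373 higher and 394 lower (349 and 583 with the uncentred length offset). The number was 266 and 228 without day 0 replicates 1 and 2 and 178 and 351 without BFP positive day 4 replicates 1 and 2. Besides Egr1 and Ms4a2, Vegfa (1.51), Rapgef4 (1.45 ± 0.15) and Klf11 (1.44) rose most. Mir6236 (-1.90 ± 0.24, uncertain as above), Baiap2 (-1.5), the red cell anion exchanger gene Slc4a1 (-1.36), Dusp14 (-1.27) and Ada (-1.18) fell most. Rapgef4 and Mir6236 had a call whichever library was left out. Without day 0 replicate 1 the calls for Klf11 (1.46, adjusted p = 0.106), Baiap2 (-1.21, adjusted p = 0.213), Slc4a1 (-1.52, adjusted p = 0.0653), Dusp14 (-1.53, adjusted p = 0.0665) and Ada (-1.13, adjusted p = 0.096) were lost. Without day 0 replicate 2 Klf11 (1.41, adjusted p = 0.105), Slc4a1 (-1.21, adjusted p = 0.196), Dusp14 (-1.0, adjusted p = 0.344) and Ada (-1.23, adjusted p = 0.0519) were not called. Without BFP positive day 4 replicate 1 Baiap2 (-1.48, adjusted p = 0.167), Slc4a1 (-0.54, adjusted p = 0.627), Dusp14 (-1.55, adjusted p = 0.184) and Ada (-0.54, adjusted p = 0.517) were not. Without replicate 2 Vegfa (1.12, adjusted p = 0.101), Klf11 (1.23, adjusted p = 0.125), Baiap2 (-1.54, adjusted p = 0.0615) and Dusp14 (-1.13, adjusted p = 0.214) were not. Thinning ended the calls for Klf11 and Ada (adjusted p = 0.432 and 0.264), and DESeq2 did not call Klf11, Baiap2, Slc4a1, Dusp14 and Ada (adjusted p = 0.134, 0.179, 0.246, 0.369 and 0.194).

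**Figure D4:**
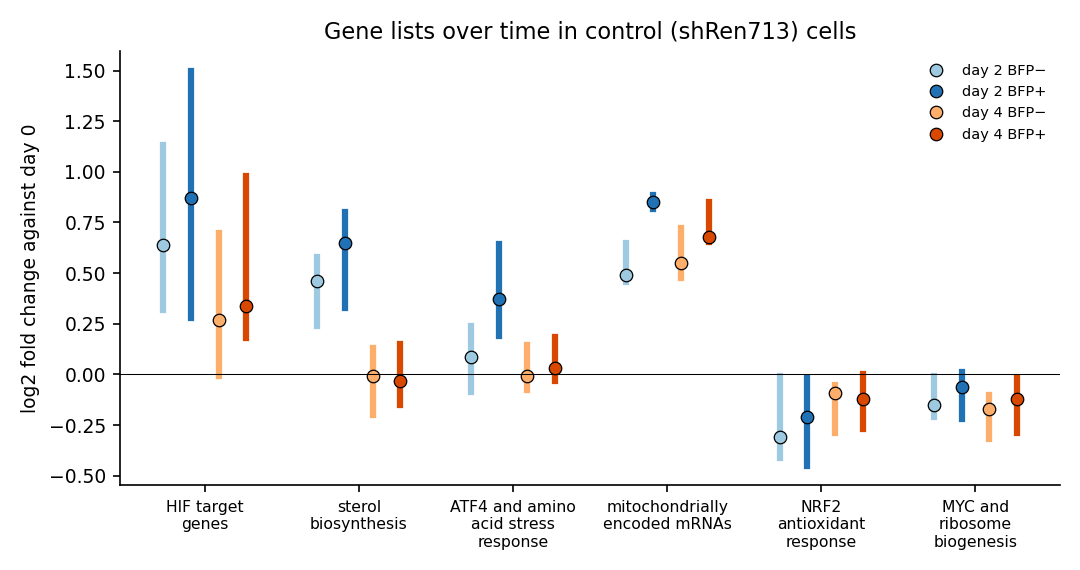
Gene lists in control cells against day 0, which was untreated and not labelled as sorted. Circles are the median log2 fold change of the members of a list, and bars are the interquartile range of its members.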

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

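In control cells the effect of induction changed with time. For 71 genes the difference between BFP positive and BFP negative cells was not the same at day 4 as at day 2. As log2 fold change at day 4 minus that at day 2, the highest at a mean of at least 5 CPM were Afap1l1 (3.81), Ctla2a (2.61), Cpne5 (2.55), Hmgn3 (2.41) and Arfgef3 (2.35). The lowest were Yap1 (-1.86), Pparg (-1.47), Dock10 (-1.40), Bcl7a (-1.38) and Pcsk6 (-1.23).

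Between the Ogdh hairpins 9 genes differed. As log2 fold change of shOgdh346 against shOgdh2081, Pi4k2b (0.67) and Rps21 (0.37) were higher. Gm15564 (-1.29), Mir6236 (-1.25), Gm26917 (-0.80), Lars2 (-0.79), Sh3bgrl (-0.71), mt-Rnr1 (-0.55) and Ppp1cb (-0.43) were lower. Gm15564, Mir6236, Gm26917 and Lars2 hold sequence that resembles ribosomal RNA, and the source of their reads is uncertain.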

How the results depend on the processing

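Thinning to equal depth, leaving out the shallow libraries, the transcript-length offsets and leaving Ogdh out of its own list were chosen after the results were seen. Ogdh itself was called in each alternative, with log2 fold changes from -2.246 to -2.057 (-2.236 to -2.14 with 1 library left out), and no named gene and no list called over both hairpins changed direction. The list of mitochondrially encoded mRNAs, called higher in BFP positive than in BFP negative cells at day 4, turned lower without BFP negative day 4 replicate 1 (adjusted p = 0.915 by camera). DESeq2 called fewer genes: 661 over both hairpins, 377 with shOgdh346, 415 with shOgdh2081, 238 shared by them and 1 different between them. In control cells DESeq2 called 223 for BFP positive against negative cells at day 2, 3 at day 4 and 22 for the difference between the days. Against day 0 it called 301 and 196 in BFP negative cells at days 2 and 4, and 792 and 227 in BFP positive cells. Thinning every library to 913482 counts gave 759 over both hairpins, 414 with shOgdh346, 506 with shOgdh2081 and 217 shared. In control cells thinning gave 199 at day 2, 2 at day 4 and 16 for the difference, 255 and 173 against day 0 in BFP negative cells, and 745 and 249 in BFP positive cells. Fits with only the groups compared gave 1814 for shOgdh346, 35 for the difference between hairpins and 1336 for BFP positive cells at day 4 against day 0. Without a filter on low counts the difference between hairpins was 20 genes. Replicate numbers did not pair the samples (21 correlations between groups, -0.08 to 0.15, median 0.01), and with the replicate block the difference between hairpins was 14 genes and the mean comparison 1850. Leaving out the shallow library of each hairpin gave 693 for shOgdh346, 668 for shOgdh2081 and 370 shared. With 1 library left out at a time, the numbers ran from 461 to 1468 over both hairpins, 369 to 736 with shOgdh346, 337 to 732 with shOgdh2081, 204 to 519 shared and 0 to 24 between hairpins (edgeR, with 602 at unadjusted p < 0.05 where it was 0 and 1 by DESeq2 on all libraries). They ran from 233 to 623 for BFP positive against negative cells at day 2, 3 to 16 at day 4 and 30 to 91 for the difference. Against day 0 they ran from 330 to 1230 and 222 to 1023 in BFP negative cells at days 2 and 4, and from 860 to 1373 and 178 to 351 in BFP positive cells. Of 16 lists called over both hairpins, 6 were called with an estimated correlation, 9 after thinning, 10 with BFP negative cells as the control and 11 to 16 with 1 library left out. Without Ogdh in its own list the 2-oxoacid dehydrogenase complexes were not called (adjusted p = 0.251), and 15 lists were. Among calls for named genes, 70 were lost and 121 kept with DESeq2, and 66 were lost and 103 kept with libraries thinned, where the rest did not pass the filter. For knockdown 22 were lost and 94 kept with BFP negative cells as the control, and 21 were lost and 95 kept without the shallow libraries. The cause of these shifts was not tested, apart from the depth that thinning and the shallow libraries address.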

Other observations

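The cells expressed genes of the erythroid, mast cell and progenitor lineages. Gata1 (295 to 353 CPM), Klf1 (179 to 256 CPM) and Epor (140 to 211 CPM), which drive red cell development, were high in every library, as were Kit (464 to 578 CPM) and Myb (536 to 897 CPM), genes of progenitors. Hdc (299 to 348 CPM), the enzyme that makes histamine, and Il1rl1 (138 to 342 CPM), the receptor for interleukin 33, mark mast cells and basophils. Elane, Lyz2, Itgam and Cd3e, genes of neutrophils, monocytes and T cells, had 0 of 48249780 counts, a limit of 0.0622 CPM over all libraries. Mpo, Cd34 and Csf1r had 1, 2 and 3 counts, though Cd34 is a progenitor gene like Kit and Myb. Gene Ontology terms, tested after the lists were seen, were called lower for 43 and higher for 1 of 2166 with Ogdh knockdown. Genes of respiratory chain complex I (13 of 43 fell, median -0.24, camera adjusted p = 4.02e-05), of the proteasome complex (25 of 61 fell, median -0.19, camera adjusted p = 8.14e-05) and of the methylosome (10 of 13 fell, median -0.30, camera adjusted p = 0.000398) were among the lower ones. Each of these was lost (adjusted p = 0.871 with an estimated correlation).

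The patterns weighed here, the length offset and the shallow-library fit were chosen after seeing results. With Ogdh knockdown camera called oxidative phosphorylation, ribosome biogenesis and DNA replication lower and mitosis and chromatin dioxygenases higher. With an estimated correlation (0.288 and 0.078) the calls for oxidative phosphorylation and chromatin dioxygenases were lost (adjusted p = 0.181 and 0.0685). The other 3 were kept. A transcript length trend between libraries is a candidate explanation, since the lists differ in length, but 5 of 5 lists kept their camera call with a transcript-length offset. The shallow shOgdh libraries are another, and 5 of 5 lists kept the call without them. For none of the 5 lists can genes moving together for a reason outside the contrast be told apart from knockdown. No uninduced Ogdh hairpin cells were sequenced. Ribosome biogenesis and DNA replication genes also fell in control BFP positive cells at day 4 against day 0 (10 and 9). An effect of lost 2-oxoglutarate dehydrogenase activity may underlie these moves and was not measured here.

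Nf1, which a hairpin silences in this line, was higher with both Ogdh hairpins. Competition from any induced hairpin could relieve that silencing, but Nf1 was not higher in control BFP positive than in BFP negative cells at day 4 (-0.16 ± 0.12). A length trend was tested too, and Nf1 kept its rise with the length offset (0.79 ± 0.10). Relief of every hairpin of the line by the Ogdh hairpins was weighed with Kmt2c (0.14 ± 0.09), but how far its hairpin silences Kmt2c in this line is not given in the sources used here, so that stays open. A rise in Nf1 transcription stays open as well.

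Of 14 erythroid and megakaryocyte genes 8 were higher with Ogdh knockdown than in control BFP positive cells, and the call for the list was lost (adjusted p = 0.052 with an estimated correlation and 0.0998 against BFP negative cells). In control BFP positive cells the beta globin genes Hbb-bt (-1.0) and Hbb-bs (-0.73) were lower than in BFP negative cells. Hbb-bt was not called without BFP positive replicate 1 or 2. That low control level may account for part of the rise of the hemoglobin genes (near-identical copies), whose median was 0.52 against BFP positive and 0.18 against BFP negative cells. Against BFP negative cells Hbb-bs went the other way (-0.21 ± 0.08, adjusted p = 0.0627), and neither it nor Hba-a1 (0.13, adjusted p = 0.235) passed. Hba-a2 kept its rise (0.53 and 0.54 ± 0.11), but may share reads with Hba-a1 and decides nothing. The low control level did not account for the called members other than hemoglobin genes. Their median was 1.01 against BFP positive and 0.84 against BFP negative cells. What raised these genes was not tested.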
